A study of Mus musculus with 4 samples.

How the data were processed

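The deposited values are UMI counts per gene and barcode, and the counts were made by the authors with fastp and STARsolo 2.7.10a against mm10, per the submitters' processing notes. The extraction label describes BD Rhapsody whole-transcriptome libraries after enzyme digestion and viability staining, while the description label names 10x Genomics, and the 27-base barcodes fit the former. The authors' barcode filter left a lowest total of 1501 UMIs in both control libraries and 500 in both PD libraries, so the controls lack cells of low depth. In cHet_PD 33.7% of barcodes and in cKO_PD 25.0% lay under the higher floor. The number of animals behind each library is not stated. Of 31253 gene identifiers, 31107 were found in GENCODE M21, and 91 symbols were shared by more than 1 identifier.

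Of 33854 barcodes, 31148 were kept: 90.3% of cHet_control, 98.8% of cHet_PD, 82.2% of cKO_control and 98.7% of cKO_PD. Barcodes needed 200 genes and at most 20% mitochondrial UMIs, and that cap removed 9.65%, 1.03%, 17.7% and 1.12%. Median UMIs per deposited barcode were 5292, 2934, 5076 and 2509, median genes 1879, 1341.5, 1794 and 1183, and median mitochondrial shares 10.1%, 5.39%, 11.9% and 5.82%. Scrublet, at an expected rate of 5%, called 2 doublets, too few to be believed, so doublets were in effect not removed. Cells were scaled to 10000 UMIs, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave clusters (seed 1). Clusters with at least 100 CPM of Ptprc were clustered again. A cluster was named by 3 markers of a type among its top 50 genes with 1 in the top 10, with 50 CPM added before ranking, and Itga9 was kept out of clustering. Clusters were drawn with the same genes that are compared, so neither their defining genes nor their sizes are given as tests. Unnamed cells were 17.7%, 18.5%, 32.9% and 8.11%, and cycling cells of no named type 5.14%, 5.64%, 6.22% and 5.54%.

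Cells of a class were summed per library and given as CPM, the share of the class's UMIs scaled as 100 times the UMIs per 10000, where the class held at least 40 cells. A gene was called by size where it was at least 2-fold apart with 10 CPM added, held 50 UMIs in 1 of the libraries and its 95% interval excluded 1. Genes could be named in the text without that fold, where they held 50 UMIs and lay in 10% of cells in the higher library, the interval excluded 1 and the CPM there was at least 0.2 of that in the highest class. Mitochondrial, ribosomal, hemoglobin, immunoglobulin and T cell receptor genes, sex-linked marker genes and predicted genes were not named. Intervals hold counting error only, not differences between animals. Folds against 0 UMIs are bounds from 3 counts. Neutrophils were compared between PD libraries only, since the controls held 35 and 25. Dendritic cells were too few for gene values. Genes named in the text are the largest of each pair among those that could be named, 12 genes set in advance, and the largest members of the lists. Some results that met these rules are not reported here. No paired analysis was possible because each group was 1 library.

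The 24 gene lists were fixed before the data were examined: inflammatory cytokines and chemokines, NF-kB and inflammasome components, alternative activation and tissue-resident macrophage genes, MHC class II presentation, interferon response, osteoclast differentiation, lipid-associated and scar-type macrophage genes, complement and phagocytic receptors, integrin subunits, integrin α9β1 ligands, matrix metalloproteinases with cathepsins and inhibitors, glycolysis and hypoxia, oxidative phosphorylation, neutrophil granule and maturation genes, fibrillar collagens and matrix assembly, inflammatory fibroblast genes, osteoclastogenic and osteogenic regulators, epithelial barrier and differentiation, epithelial alarm and antimicrobial genes, endothelial activation and adhesion, type 17 and cytotoxic lymphocyte genes, regulatory T cell and checkpoint genes, dissociation and immediate early response, and cell cycle. A member was measured with 20 UMIs and counted from 1.5-fold, and medians were placed among 10000 random lists matched in 20 expression bins. Medians are printed without subtracting the median of all genes of the pair, so a small one may lie near that background. For the 29 medians with members at 0 UMIs in 1 library, putting these at their bounds gave a largest move of 0.154 and turned the sign of 0. Most of these medians did not move.

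Several choices were made after the data were seen: 40 cells per class in place of 50, the second clustering of immune clusters and the naming rule, the common UMI floor, the removal of the top 5% of doublet scores, thinning with fixed list members, and the bone-forming transcript set. An earlier version of the work fixed the list members in every setting after the planned thinning had turned the interferon median of cKO phagocytes, and that step was undone. Fixed members are now only an added alternative. Scrublet was run on 1 thread, since its scores differed between runs on several threads.

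A self-test drew Poisson counts for each pair from the pooled phagocyte profile, with 200 of 31253 genes changed, so it holds no variation between animals or cells. Of 50 genes changed 2-fold, 23, 20, 16 and 25 were found for cHet PD, cKO PD, PD and control pairs, and at 4-fold 49, 48, 50 and 49. Unchanged genes called were 4, 0, 6 and 2. A list of 25 genes raised 2-fold gave median log2 folds of 1.00, 1.05, 0.89 and 0.93, and 12, 10, 10 and 7 of 200 unchanged lists fell outside the middle 95% of random lists. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.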

Results

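Single-cell transcripts of mouse gingiva were counted in 4 libraries, 1 per group, so no difference has a replicate check and no p-value is given. The groups crossed a genotype label (Itga9-Lyz2-cHet or Itga9-Lyz2-cKO) with treatment: control, or periodontitis (PD) brought on by a silk ligature and Porphyromonas gingivalis at the upper second molar, with gingiva taken after 14 days. The cHet_control library held 58702911 unique molecular identifiers (UMIs) in 8767 barcodes and cHet_PD held 36231795 in 9072. The cKO_control library held 62914870 in 9331 barcodes and cKO_PD held 21368197 in 6684. The deepest-filtered libraries were the controls: the lowest UMI total of a deposited barcode was 1501 in both control libraries and 500 in both PD libraries. Filtering kept 7915, 8966, 7673 and 6594 cells in the order cHet_control, cHet_PD, cKO_control and cKO_PD, which is the order of every set of 4 values here.

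Itga9, the integrin subunit the genotype labels name, was lower in mononuclear phagocytes (monocytes and macrophages) of the cKO libraries. Its level was 145 CPM (95% interval 106 to 193) in cHet_control and 47.7 (28.2 to 75.3) in cKO_control, a ratio of 0.330 (0.180 to 0.580). In the PD libraries it was 91.8 CPM (74.5 to 112) in cHet_PD and 20.1 (9.18 to 38.1) in cKO_PD, a ratio of 0.219 (0.0971 to 0.432). Endothelial cells, another class that held Itga9, gave 104, 46.9, 121 and 81.2 CPM, and fibroblasts 90.5, 11.7, 32.6 and 45.3. In fibroblasts the ratio between the controls was 0.360 (0.223 to 0.562) and that between the PD libraries 3.87 (1.96 to 7.71), so a lower level in cKO_control was not particular to phagocytes. Neutrophils, which express Lyz2, gave 1, 0, 0 and 0 Itga9 UMIs, so the gene could not be compared there.

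Itga9 UMIs were found in 44.2% of cHet_control phagocytes, 23.2% of cHet_PD, 22.0% of cKO_control and 2.42% of cKO_PD. Epithelial cells, taken as the background, gave 0.380%, 0.170%, 0.427% and 0.125%. Median depths were 7393, 4121.5, 6502 and 3154 UMIs in phagocytes and 6130.5, 3213, 5874.5 and 2707 in epithelium. Thinned to 1000 UMIs per cell, with 17 cHet_PD and 12 cKO_PD phagocytes left out as too shallow, the shares were 16.3%, 8.37%, 1.69% and 0%. Clusters within the class differed: the monocyte-type cluster led by Fn1 and Vcan gave 0 Itga9 UMIs in both PD libraries, and it made up 75.0% of cKO_PD phagocytes against 18.6% of cHet_PD. Within the resident-type cluster led by Ccl8, Itga9 was 160 CPM (115 to 217) in cHet_control and 53.1 (30.9 to 85.0) in cKO_control. Within the cluster led by Pdpn and Arg1 it was 104 (84.1 to 128) in cHet_PD and 21.4 (2.60 to 77.4) in cKO_PD, where 24 cells held 2 UMIs. The 7 resident-type cells of cKO_PD held 7 UMIs, 340.5 CPM (137 to 701), against 127 CPM (41.4 to 297) in 11 cells of cHet_PD, so the direction was opposite there, on few cells. Reads of this kind lie mostly near the 3' end of a transcript and the labels do not say which part of the gene was changed, so UMIs outside that part may remain and then check nothing. The gene lies on chromosome 9 from 118606690 to 118901003 (mm10, ENSMUSG00000039115).

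**Figure D1:**
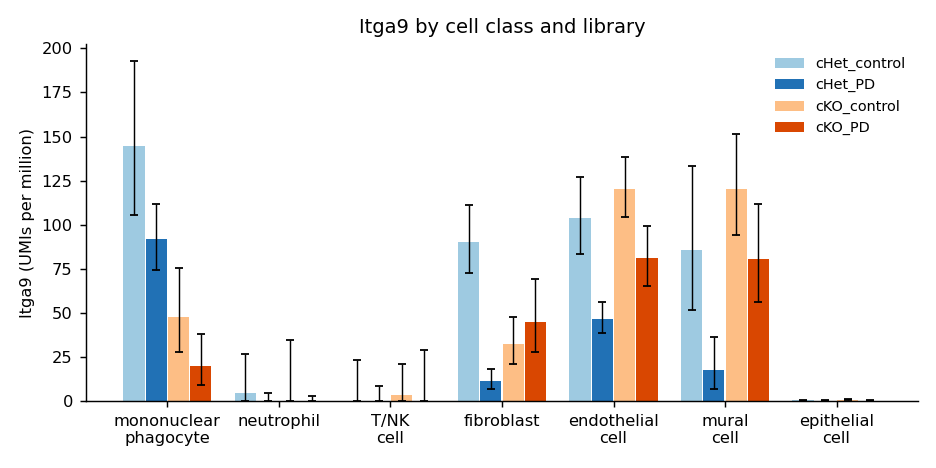
Itga9 in CPM (vertical axis) for 7 cell classes, with 1 bar per library and exact 95% Poisson intervals. In mononuclear phagocytes both cKO bars (47.7 and 20.1) lie below both cHet bars (145 and 91.8), while in endothelial cells all 4 libraries lie between 46.9 and 121.

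The first comparison, cHet_PD against cHet_control, asked what ligature periodontitis did in the gingiva of cHet animals. Neutrophils made up 7.93% of cells (7.38 to 8.51) against 0.442% (0.308 to 0.614), a ratio of 17.9 (12.8 to 26.0). Of the 35 control neutrophils 22 lay in the immature cluster led by Ltf and Ngp, and without immature clusters the shares were 7.70% and 0.0758%. Mononuclear phagocytes made up 2.45% (2.14 to 2.80) against 0.543% (0.393 to 0.731), a ratio of 4.52 (3.25 to 6.42), and T and natural killer (T/NK) cells had a ratio of 4.04 (2.95 to 5.62). Endothelial cells (5.06, 4.23 to 6.09), fibroblasts (2.51, 2.07 to 3.06) and dendritic cells (2.27, 1.45 to 3.65) also held larger shares, and epithelial cells a smaller one (0.691, 0.663 to 0.720). The lower UMI floor of the PD libraries bears on these shares: at the floor of the controls the log2 ratio for neutrophils was 1.39 against 4.16. Among named immune cells alone, phagocytes were the smaller part in PD, 17.6% against 25.6%.

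In phagocytes of cHet_PD, Arg1, Pdpn, Spp1 and 2 neutrophil-attracting chemokines were among the highest genes. Arg1, an arginine-degrading enzyme of macrophages in healing tissue, gave 1070 CPM against 0 UMIs in the control, at least 113-fold higher. The neutrophil attractants Cxcl1 (93.0-fold, 47.1 to 216) and Cxcl3 (45.3-fold, 27.4 to 81.2), the matrix protein Spp1 (53.1-fold, 32.7 to 93.1), the membrane glycoprotein Pdpn (115-fold, 44.8 to 422) and Flrt3 (157-fold from 1 UMI, 28.1 to 6228) completed the 6 largest. The 6 largest the other way were Mt2, a metallothionein (26.8-fold lower, 19.7 to 37.3), the resident macrophage genes Mgl2 (36.3-fold, 15.8 to 103), Cbr2 (20.1-fold, 12.9 to 32.8), Cd163 (18.0-fold, 12.1 to 27.8) and Lyve1 (17-fold, 12.1 to 24.5), and complement C4b (23.0-fold, 12.8 to 44.8). By the rule of size, 488 genes were at least 2-fold higher and 300 at least 2-fold lower of 3307 considered. With TMM scaling, which moved all phagocyte log2 folds of this pair by 0.30, the higher share of those calls was 78.8% against 61.9%, and after thinning it was 78.2%.

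The clusters behind the phagocyte class differed between these libraries. In cHet_control 79.1% of phagocytes lay in the resident-type cluster, and in cHet_PD 76.4% lay in the cluster led by Pdpn, Arg1 and Spp1, which the clustering drew partly from those same genes. Of the inflammatory cytokine and chemokine list, 17 of 25 measured members were at least 1.5-fold higher and 3 lower (median log2 fold 1.42, at percentile 100 of 10000 random lists matched on expression). Of the lipid-associated macrophage list 21 of 26 were higher, with Gpnmb 28.2-fold higher (14.3 to 65.7) and Apoe 1.99-fold lower (1.82 to 2.18, median 1.47). Of the alternative activation and resident macrophage list 20 of 26 were lower (median -2.06), and of MHC class II presentation 8 of 10, with H2-Eb1 3.92-fold lower (3.59 to 4.29, median -1.17). The ligands of integrin α9β1 made by phagocytes were higher in 7 of 10 (median 1.71), led by Spp1 and the protease Adam8 (10.5-fold, 6.89 to 16.9). Glycolysis and hypoxia genes were higher in 15 of 24 (median 0.95), with Hif1a 8.24-fold (5.61 to 12.6). Medians were smaller for integrin subunits (0.76), matrix metalloproteinases and cathepsins (0.77), interferon response (0.47), complement receptors (0.41), osteoclast differentiation (0.21), NF-kB components (0.20) and oxidative phosphorylation (0.08). The dissociation and immediate early list was lower in 17 of 28 (median -0.99), with Egr1 6.15-fold lower (5.46 to 6.93).

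Stromal and epithelial cells of cHet_PD held alarm and adhesion transcripts. In fibroblasts 29 of 34 inflammatory fibroblast genes were higher (median 1.69), and the interleukin-33 receptor Il1rl1 (42.6-fold, 33.0 to 55.9) and the pentraxin Ptx3 (38.6-fold, 28.2 to 54.5) stood highest of the genes that could be named. The dissociation and immediate early list was lower in 14 of 28 in fibroblasts (median -0.58). Angptl7 was at least 167-fold lower in fibroblasts and Pcsk2 was 305-fold lower, from 197 UMIs to 1 (54.1 to 12113). Fibroblast Tnfsf11, the osteoclast differentiation factor RANKL, was 44.8 CPM against 6.04 (7.42-fold, 3.24 to 20.9), and its decoy receptor Tnfrsf11b was 81.8 against 20.1 (4.07-fold, 2.53 to 6.89). Fibrillar collagen and matrix genes were higher in 16 of 32 (median 0.61). Epithelial alarm and antimicrobial genes were higher in 22 of 33 (median 1.11), while barrier genes had a median of -0.05. The epithelial cells lay in different clusters: that led by Aqp3 and Serpinb2 made up 41.0% of cHet_PD and 0.285% of cHet_control, that led by Krt76 and Krt24 1.31% and 14.8%, and that led by Krt15 3.93% and 27.3%. The largest epithelial differences were Tmprss11g (44.3-fold higher, 39.4 to 50.0) and Phlda1 (27.4-fold, 25.6 to 29.5), against the keratin Krt24 (12.3-fold lower, 11.9 to 12.7) and Mt2 (11.3-fold, 11.1 to 11.6). Endothelial activation genes were higher in 19 of 30 (median 0.86), with Il6 at 773 CPM against 71.7. Interferon response genes were higher in 31 of 38 in endothelium (median 1.37) and 24 of 34 in fibroblasts (median 1.15). In T/NK cells the regulatory and checkpoint list was higher in 11 of 16 (median 1.31). The type 17 and cytotoxic list had a median of 0.25, near the 0.22 of all 1722 genes considered, with Il17f at 171 CPM against 12.8. The transcription factor genes Irf8 (25.1-fold, 6.81 to 209) and Bcl6 (21.9-fold, 3.78 to 880) stood highest in T/NK cells, from 2 UMIs and 1.

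**Figure D2:**
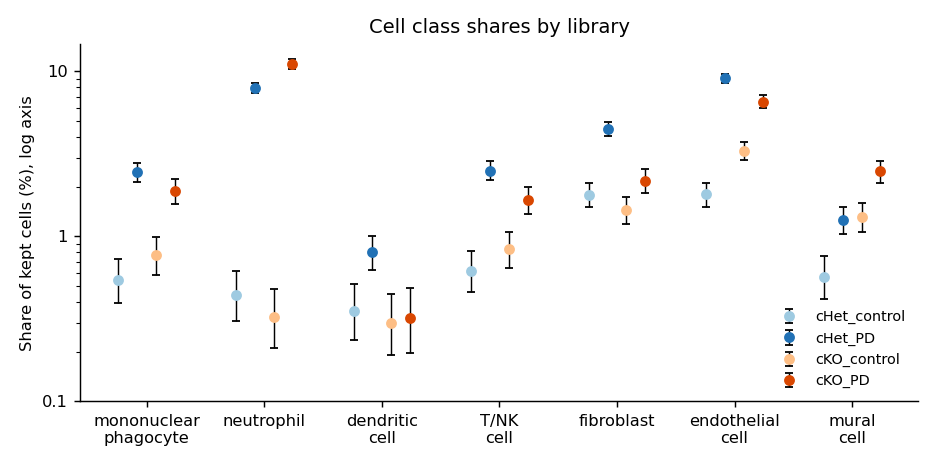
Share of kept cells in percent (vertical axis, logarithmic) for 7 cell classes, with 1 point per library and exact 95% binomial intervals. Neutrophils stand at 7.93% and 11.1% in the PD libraries against 0.442% and 0.326% in the controls, and mononuclear phagocytes at 2.45% and 1.88% against 0.543% and 0.769%.

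The next comparison, cKO_PD against cKO_control, asked the same of the cKO animals. Neutrophils made up 11.1% of cells (10.4 to 11.9) against 0.326% (0.211 to 0.481), a ratio of 34.1 (22.9 to 53.1), and without immature clusters the shares were 3.69% and 0.0521%. Phagocytes made up 1.88% (1.57 to 2.24) against 0.769% (0.586 to 0.991), a ratio of 2.45 (1.78 to 3.39), and were 12.2% against 32.8% of named immune cells. Ratios were 1.98 (1.44 to 2.74) for T/NK cells, 1.99 (1.70 to 2.33) for endothelium and 1.5 (1.16 to 1.94) for fibroblasts. At the UMI floor of the controls the log2 ratio for T/NK cells turned to -1.07, so their direction rests on cells of low depth. The log2 ratio of fibroblast share, cKO_PD vs cKO_control, was -0.0362 at clustering resolution 2.0.

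In phagocytes of cKO_PD, Ly6c2, Acod1 and Cxcl3 were among the highest genes and the chemokines Ccl12, Ccl8 and Ccl7 among the lowest. Ly6c2, a surface marker of blood monocytes, was 117-fold higher (56.4 to 291) and Acod1, the itaconate-making enzyme, 76.8-fold (41.6 to 161). Cxcl3 was 156-fold higher from 2 UMIs (42.9 to 1292), Sgms2 61.3-fold (23.7 to 227) and Cdk5r1 at least 38.2-fold. The chemokines Ccl12 (394-fold, 70.2 to 15606) and Ccl8 (267-fold, 47.4 to 10591) were lower and held 1 UMI each in cKO_PD, as did the transporter Slco2b1 (103-fold, 18.0 to 4124). Ccl7 was 66.9-fold lower (33.7 to 156), complement C1qa 21.5-fold (13 to 38.1) and Rcan1 20.5-fold (10.9 to 43.6). In cKO_control 81.4% of phagocytes lay in the resident-type cluster and in cKO_PD 75.0% in the monocyte-type cluster. Of 2001 genes considered, 380 were at least 2-fold higher and 329 lower, and the higher share went from 53.6% to 71.1% after thinning.

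Gene groups of cKO_PD phagocytes followed partly different directions. Cell cycle genes were higher in 16 of 17 (median 2.10), with Mki67 13.4-fold higher (6.59 to 31.7), and oxidative phosphorylation genes in 21 of 33 (median 0.85). Glycolysis and hypoxia genes were higher in 12 of 22 (median 0.89). MHC class II genes were lower in 9 of 10 (median -2.15), with H2-Eb1 11.9-fold lower (10.1 to 14.0), resident macrophage genes in 14 of 21 (median -2.30) and complement receptors in 13 of 23 (median -1.02). The dissociation and immediate early list, a sign of handling, was lower in 25 of 28 (median -1.51). The inflammatory list went both ways, 6 members higher and 9 lower of 22 (median -0.47), as Tnf was 321 CPM against 1546 and Il6 172 against 10.6. The interferon list was lower in 16 of 28 (median -0.80), but its median was 0.60 in cells thinned to 1000 UMIs, where the measured members are chosen anew. With the members kept as without thinning, an alternative added after that turn was seen, it was -0.21, so its direction depended on which members were measured. The lipid-associated list had a median of 0.01, integrin subunits -0.09, α9β1 ligands 0.50, metalloproteinases and cathepsins 0.45, osteoclast differentiation -0.46 and NF-kB components 0.13. The ligand gene Fn1 was 81.4-fold higher (45.3 to 163) and Vcam1 16.5-fold lower (10.8 to 26.3).

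In fibroblasts of cKO_PD the bone-resorption and bone-matrix genes Mmp13 (392-fold, 190 to 976) and Ibsp (231-fold, 112 to 576) stood highest, and Inmt (752-fold lower to 1 UMI, 135 to 29718) and Apod (136-fold, 99.8 to 190) lowest. Inflammatory fibroblast genes were higher in 19 of 30 (median 0.97), collagens in 21 of 32 (median 1.19) and regulators of bone cells in 13 of 24 (median 0.89), with Bglap at 491 CPM against 1.25. Bone-forming cell transcripts as a set stood at 3587 CPM in this class against 40.1 in cKO_control, so these values hold a difference in which cells the class held. TMM scaling moved all fibroblast log2 folds of this pair by 0.40. Fibroblast Tnfsf11 was 64.7 CPM against 5.01 (12.9-fold, 4.55 to 50.4). In epithelium the cluster led by BC037156 and Odam, which Tmprss11g also marks, made up 23.2% of cKO_PD and 2.80% of cKO_control. BC037156 (8.16-fold, 8.08 to 8.24) and Tmprss11g (10.5-fold, 9.60 to 11.5) were higher, Krt2 (16.2-fold, 15.1 to 17.4) and Lgals7 (11-fold, 10.5 to 11.5) lower, and alarm genes were higher in 19 of 30 (median 0.75), as was the dissociation and immediate early list (18 of 28, median 0.94). Endothelial activation genes were higher in 14 of 29 (median 0.55). T/NK cells held more of the chemokine receptor Cxcr4 (10.9-fold, 8.09 to 15) and of Rdm1 (8.76-fold, 5.96 to 13.2), with a median of 0.93 for the regulatory list and 0.52 for the type 17 list, while the dissociation and immediate early list was lower in 17 of 26 (median -0.94). Mup4 and Obp1a in T/NK cells were at least 15.4-fold and 12.2-fold lower. They may be free RNA in cKO_control, where Mup4 UMIs lay in 30.5% of phagocytes, 33.0% of epithelial cells and 43.2% of fibroblasts. Doublets were in effect not removed and could bring them too.

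Across genes of phagocytes, the PD-to-control log2 folds of the 2 genotypes had a Pearson r of 0.595 over 3362 genes, which are not independent replicates. Both genotypes held 173 of the higher genes (55.2 if the lists were independent) and 149 of the lower (29.4), and 9 genes passed the rule in opposite directions. The values of r were 0.823 in epithelium, 0.755 in endothelium, 0.620 in fibroblasts and 0.614 in T/NK cells. The difference between the genotypes' log2 folds, cKO minus cHet, was, among the genes reported here, largest upward for Ly6c2 (6.75), F5 (5.37) and Fn1 (4.67) in phagocytes. It was largest downward for Cxcl1 (-6.53), Ccl7 (-5.46), Ccl12 (-4.96) and Gpnmb (-4.37), and the Cxcl1 value rests in part on 6 cells of cKO_control. Between the controls, Fn1 was already lower in cKO_control, and Cxcl1, Ccl12 and Gpnmb already higher. The values of these genes therefore hold a difference between the controls too, not only between the PD libraries. For gene groups in phagocytes the median of the per-gene differences was 2.09 for the cell cycle, 0.71 for oxidative phosphorylation, -1.69 for the lipid-associated list, -1.46 for inflammatory cytokines, -1.38 for MHC class II, -1.20 for the interferon response and -0.70 for the dissociation and immediate early list. These differences have no residual degrees of freedom and are values only.

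The comparison of the PD libraries, cKO_PD against cHet_PD, asked how inflamed gingiva differed between the genotype labels. Neutrophils held a larger share in cKO_PD (ratio 1.40, 1.26 to 1.56), and at the UMI floor of the controls the log2 ratio was 2.46 against 0.49. Without the immature granulocyte clusters the direction was opposite, with 3.69% of cells in cKO_PD and 7.70% in cHet_PD. An immune cluster of no named type led by Rsad2 and Ifit1, 103 cells of cHet_PD and 0 of cKO_PD, is not part of these shares. Phagocytes (0.766, 0.610 to 0.959), T/NK cells (0.662, 0.521 to 0.835), fibroblasts (0.485, 0.398 to 0.588) and dendritic cells (0.397, 0.232 to 0.652) held smaller shares in cKO_PD. The clusters within the neutrophils differed: 55.7% of those of cHet_PD lay in a cluster led by Csf3r and Cxcr2 and 37.7% in one led by Acod1 and Ccrl2. In cKO_PD 49.5% lay in a cluster led by Ltf and Ngp, 25.2% in one led by Retnlg and Mmp8 and 17.3% in one led by Chil3, Camp and Mki67. With 1 library per group, a cluster held mostly by 1 library may stand for that library rather than for a cell type.

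**Figure D3:**
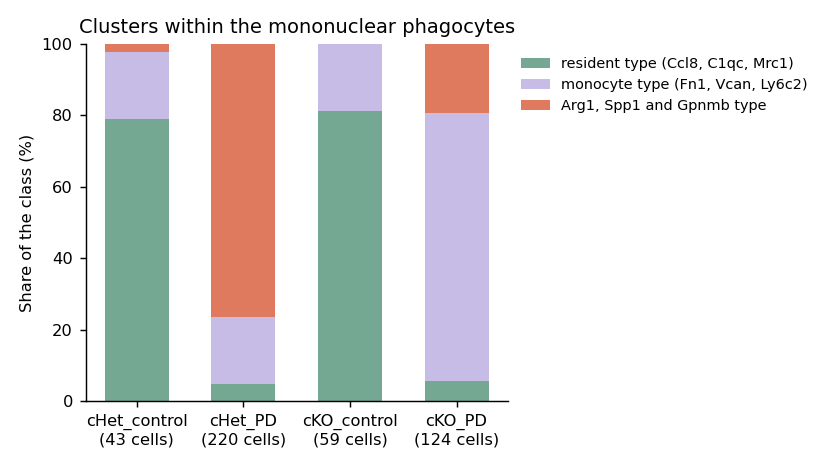
Share of the mononuclear phagocytes in percent (vertical axis) that lay in each of 3 clusters, with 1 stacked bar per library and the number of cells under it. The Arg1, Spp1 and Gpnmb type makes up 76.4% of cHet_PD and 19.4% of cKO_PD, and the monocyte type 18.6% and 75.0%.

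In phagocytes of cKO_PD, cell cycle genes and Ly6c2 were higher and Arg1, Ctsk and Pdpn lower than in cHet_PD. The highest of those reported here were Pclaf (16.7-fold, 8.82 to 34.8), Ube2c (14.9-fold, 8.04 to 30.1) and Top2a (7.29-fold, 4.88 to 11.2), which act in dividing cells, the linker histone H1f0 (8.61-fold, 5.53 to 13.9) and Ly6c2 (7.04-fold, 6.20 to 8). The 6 lowest were Arg1 (22.8-fold lower, 14.9 to 37.0), the cathepsin Ctsk (24.6-fold, 11.2 to 67.4), Ccl7 (19.9-fold, 9.99 to 46.4), Pdpn (11.2-fold, 8.59 to 14.8), the elastase Mmp12 (8.19-fold, 5.34 to 13.2) and Cxcl9 (49.1-fold to 1 UMI, 8.65 to 1956). Ctsk turned higher in cKO_PD, with log2 folds of 1.00 and 1.5, when cells above 10% mitochondrial UMIs or the top 5% of doublet scores were left out. Tnf was 0.303 times its cHet_PD level (0.253 to 0.361), Il1b 1.55 times (1.46 to 1.64) and Il6 3.67 times (2.54 to 5.35). Lyz2, the gene named with Itga9 in the labels, was 0.547 times (0.523 to 0.572) and Itgb1, the partner subunit, 0.684 times (0.560 to 0.831). Of 3285 genes considered, 128 were at least 2-fold higher and 255 lower. TMM scaling moved all log2 folds of this pair by -0.16 and gave 21.7% higher against 33.4%. The cluster led by Pdpn, Arg1 and Spp1 made up 76.4% of cHet_PD phagocytes and 19.4% of cKO_PD. The monocyte-type cluster, which Ly6c2 also marks, made up 18.6% and 75.0%. Values of the whole class hold that difference too, and the clusters were drawn partly from these genes.

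By gene group, phagocytes of cKO_PD held less of the lipid-associated list (22 of 26 lower, 0 higher, median -1.41), inflammatory cytokines (18 of 25, median -1.24), metalloproteinases and cathepsins (9 of 15, median -1.11) and interferon response (30 of 37, median -1.0). Resident and alternative activation genes (16 of 22 lower, median -0.90), MHC class II (6 of 10, median -0.89), α9β1 ligands (6 of 10, median -0.85) and complement receptors (12 of 24, median -0.59) were lower too. Smaller medians were found for glycolysis (-0.42), the immediate early list (-0.39), osteoclast differentiation (-0.37) and integrin subunits (-0.29). The median of osteoclast differentiation in mononuclear phagocyte, cKO_PD vs cHet_PD, turned to 0.0800 under a 10% mitochondrial cap and to 0.27 without the top 5% of doublet scores. Cell cycle genes were higher in 18 of 20 (median 1.78), and oxidative phosphorylation (0.37) and NF-kB components (0.20) had medians above 0. How far the medians of most lists followed the different cluster make-up of the class was not tested. Only the interferon and inflammatory lists were run within the monocyte-type and the Arg1 and Spp1 clusters, and both kept their direction there. Interferon genes were lower in 13 of 13 members in the monocyte-type cluster (median -1.23) and in 26 of 33 in the Arg1 and Spp1 cluster (median -1.39). Inflammatory cytokines had medians of -1.47 and -1.19 in those clusters.

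The interferon response was lower in cKO_PD in all 6 classes compared, with 0 members at least 1.5-fold higher in each. The medians were -2.27 in neutrophils (23 of 24 lower), -1.21 in fibroblasts (29 of 32), -1.07 in endothelium (32 of 38), -0.88 in T/NK cells (9 of 15) and -0.25 in epithelium (8 of 40), beside -1.0 in phagocytes. The antiviral gene Rsad2 was 40.3-fold lower in neutrophils (24.1 to 72.7).

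**Figure D4:**
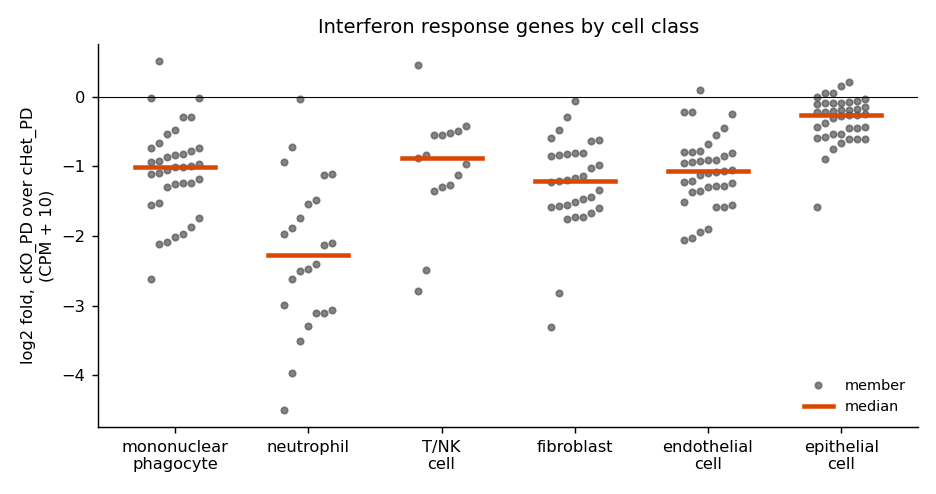
Log2 fold of each interferon response gene, cKO_PD over cHet_PD with 10 CPM added (vertical axis), in 6 cell classes, with 1 point per gene and a bar at the median. The medians run from -2.27 in neutrophils to -0.25 in epithelial cells.

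Neutrophils of cKO_PD held more of the granule genes Camp (13-fold, 11.4 to 14.8) and Chil3 (10.0-fold, 9.06 to 11.1), and 17 of 24 granule and maturation genes were higher (median 1.28). Rsad2 and Wfdc17 (28.2-fold, 20.0 to 40.9) were lowest, and inflammatory cytokines (17 of 19, median -2.09), NF-kB components (17 of 25, median -1.09) and immediate early genes (20 of 28, median -1.25) were lower. Within the Csf3r and the Acod1 clusters the inflammatory medians were 0.11 and 0.18, and within the Retnlg and Mmp8 cluster 7 of 10 members were higher and 0 lower (median 0.96). In the Csf3r cluster 6 of 15 members were lower and 3 higher, and in the Acod1 cluster 3 of 12 were lower and 3 higher. Their cKO_PD cells numbered 28 and 30. The clusters led by Ltf and Ngp and by Chil3, Camp and Mki67 were not run. Clusters were also drawn partly from the compared genes, so how far the class-wide difference followed them is not decided. Oxidative phosphorylation genes were higher in 21 of 37 (median 0.60). The rule of size gave 530 genes higher and 492 lower of 3506.

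Fibroblasts of cKO_PD held bone-matrix transcripts: Dmp1 was 35.5-fold higher (22.4 to 59.3), Bglap 15.8-fold (11.5 to 22.0) and Spp1 12.3-fold (11.1 to 13.6). Bone-forming cell transcripts as a set were 6.62-fold higher there (6.09 to 7.21), so the fibroblast class of cKO_PD held cells of that kind. The joint and tendon proteins Cilp (32.4-fold, 16.4 to 75.4) and Prg4 (16.2-fold, 9.01 to 32.7) were lowest. Regulators of bone cells were higher in 11 of 24 (median 0.45), while inflammatory genes (23 of 34, median -1.09) and cell cycle genes (20 of 24, median -0.97) were lower. Collagens had a median of -0.23, near the -0.27 of all 4808 fibroblast genes considered. Fibroblast Tnfsf11 was 64.7 CPM against 44.8 (ratio 1.44, 0.907 to 2.25), a difference not detectable at this depth, and Tnfrsf11b was 0.553 times its cHet_PD level (0.331 to 0.883), though thinning turned its log2 fold to 0.14. In epithelium Cdo1 (5.07-fold, 4.72 to 5.46) and Sostdc1 (4.03-fold, 3.59 to 4.52) were highest and Krt4 (11.4-fold, 10.9 to 11.9) and Serpinb2 (4.68-fold, 4.40 to 4.98) lowest. Barrier genes were lower in 14 of 30 (median -0.54), alarm genes had a median of -0.22, and cell cycle genes were higher in 10 of 26 (median 0.52). The cluster led by Aqp3 and Serpinb2 made up 41.0% of cHet_PD epithelium and 8.70% of cKO_PD, and that led by BC037156, which Cdo1 also marks, 11.8% and 23.2%. In T/NK cells 5 genes were at least 2-fold higher, among them the neutrophil transcripts S100a8 and S100a9, which are named here after their values were seen. Of the genes that could be named, Tmsb4x (1.97-fold, 1.88 to 2.07) and Tex14 (1.97-fold, 1.76 to 2.21) were highest and the granzymes Gzma (62.4-fold to 1 UMI, 11.1 to 2477) and Gzmb (8.28-fold, 4.44 to 17.5) lowest. Cell cycle genes were lower in 15 of 18 T/NK members (median -1.21), and the regulatory and type 17 lists had medians of -0.51, which thinning turned to 0.12, and 0.20. Endothelial activation genes had a median of -0.16.

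The comparison of the controls, cKO_control against cHet_control, asked what the genotypes differed in without disease. The share of phagocytes had a ratio of 1.42 (0.939 to 2.15) and that of neutrophils 0.737 (0.423 to 1.27), differences not detectable at this depth. In phagocytes Cxcl1 (18.5-fold, 9.20 to 43.6), Ccl12 (7.99-fold, 5.63 to 11.7) and Gpnmb (7.37-fold, 3.54 to 17.7) were highest in cKO_control. Its 176 Cxcl1 UMIs lay in 6 of 59 cells, against 4 of 43 cells in cHet_control, so a few cells carried that fold. The endothelin receptor Ednrb (at least 48.3-fold), Retnla (at least 35.2-fold) and Lyve1 (24.1-fold, 12.8 to 51.0), genes of resident macrophages, were lowest. Inflammatory cytokines were higher in 13 of 20 (median 1.26), with Tnf 2.46-fold (2.09 to 2.90) and Il1b 2.63-fold higher (2.31 to 3), and resident macrophage genes were lower in 14 of 23 (median -0.82). The dissociation and immediate early list was higher in 4 of 28 and lower in 1 (median 0.33), and its percentile among matched lists was 99.9. NF-kB components had a median of 0.43, the lipid-associated list 0.31 and the interferon list 0.20. The rule of size gave 60 genes higher and 70 lower of 1511. The 43 phagocytes of cHet_control and 59 of cKO_control limit these values, and thinning gave 15 genes, 11 of them among the 130.

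In other control classes BC037156 was 2.74-fold higher (2.7 to 2.78) and Krt2 4.29-fold lower (4.24 to 4.34) in cKO_control epithelium. Angptl7 was 65.1-fold lower in fibroblasts (25.2 to 240), where collagens (14 of 32 lower, median -0.50) and inflammatory genes (14 of 28, median -0.57) were lower too, as was the dissociation and immediate early list (13 of 28, median -0.47). The natural killer receptor Klrk1 was 5.96-fold lower in T/NK cells (3.67 to 10.0). Mup4 in fibroblasts and T/NK cells, at least 141-fold and 19.1-fold higher, may be free RNA or doublets, as described for cKO_control.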

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

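The tests below were chosen after the results were seen, as were the patterns they weigh, and the bone and dilution tests were written last. Interferon-response transcripts were lower in cKO_PD than in cHet_PD, with thinned medians of -1.08 in phagocytes, -2.7 in neutrophils, -1.10 in fibroblasts and -1.24 in endothelium. After thinning, 5 of 5 classes stayed at or below -0.5. Class sums were already scaled to CPM, so thinning changed mainly the weight of each cell and the members measured. It therefore says little about depth per cell. Free neutrophil RNA could not bring it in the 3 classes tested (phagocytes, fibroblasts and endothelium), as the smallest excess over what it could bring was 74.4 times, in phagocytes. The genotype cannot be told apart from the library, with 1 library per genotype and treatment. The list was run within single clusters only for phagocytes and neutrophils, and not in all of theirs. What stays open is therefore the make-up of the classes, beside any difference in timing or microbial load between the animals.

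Immature granulocyte clusters led by Ltf and Ngp, by Camp and Mki67 and by Mpo and Elane held 548 cells of cKO_PD, 8.31% of kept barcodes, against 0.335% in cHet_PD. Early B cells were looked for as a sign of marrow in the tissue. Per UMI of immune clusters their transcripts stood at 0.246 (0.173 to 0.344) of cHet_PD. The value was 0.0967 (0.0432 to 0.19) without Ebf1, which fibroblasts express and which was left out afterwards. Over all kept barcodes the values were 0.867 (0.8 to 0.939) and 0.309 (0.189 to 0.484). Without Ebf1 the counts in immune clusters were 119 UMIs in cHet_PD and 9 in cKO_PD. With Ebf1 the level in immune clusters was 110, 62.8, 12.7 and 15.5 CPM. Early granule genes, which mark immature granulocytes, gave 1700, 65.4, 217 and 754 CPM in the same clusters. Both sets were highest in cHet_control, but they went opposite ways between the PD libraries. The early B cell set rested on few counts, so it cannot decide on marrow. Low depth argued poorly for the immature clusters, since 62.4% (58.2 to 66.5) of their cKO_PD cells passed the higher UMI floor. Bone-forming transcripts such as Bglap were 3.71-fold higher in cKO_PD than in cHet_PD over all kept barcodes (3.43 to 4.01). They stood at 27.1, 26.5, 3.29 and 98.5 CPM. Between the controls they did not follow the immature clusters, which held 0.455% of cHet_control and 0.326% of cKO_control. More bone in the tissue piece of cKO_PD stays open, and the genotype, with 1 library each, cannot be told apart from that.

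The macrophage cluster led by Pdpn, Arg1 and Spp1 held 168 cells of cHet_PD and 24 of cKO_PD. Dilution by other immune cells does not account for it, as its cells per fibroblast and endothelial cell stood at 0.302 (0.188 to 0.465) of cHet_PD. Lower depth in cKO_PD was not decided, as the cluster's cells were not counted after thinning. The lipid-associated list kept a median of -1.32 in phagocytes named after clustering at 1000 UMIs per cell. That value came from unthinned counts of the whole class, whose make-up also sets it. The genotype cannot be told apart from the library, with 1 of each. How far tissue sampling set the number of these macrophages stays open.

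Other differences between the genotypes were not tested. Inflammatory cytokines in phagocytes had median log2 folds of 1.42 in cHet over 25 members and -0.47 in cKO over 22, and the median of the per-gene differences was -1.46 over 26, beside -0.70 for the dissociation and immediate early list, with 17 of 28 lower. The interferon list there had 0.47 over 38 members and -0.80 over 28, the latter 0.60 after thinning with members chosen anew and -0.21 with members kept, and a median of the per-gene differences of -1.20 over 40. Top2a, needed for chromosome separation, had -0.89 and 2.59, a difference of 3.48. F5, a clotting factor gene, had -1.84 and 3.53, a difference of 5.37. Tnf had 0.75 and -2.23, a difference of -2.98. Fibroblast Cilp had 1.54 and -1.02, a difference of -2.56. Fibroblast Prg4, the lubricin gene, had 2.51 and -1.68, a difference of -4.19. Klrk1 in T/NK cells had -0.77 and 1.61, a difference of 2.39. Some clusters of no named type held a larger share of a PD library than of both controls, were not compared by gene, and are listed in part: that led by Krt1, Krt10, BC037156 and Krtdap held 1.84% of cHet_PD and 1.59% of cKO_PD. The cluster led by Mpo, Elane, Prtn3 and Ctsg held 0.880% of cKO_PD. The cluster led by Rsad2, Ifit1, Slfn4 and Slfn5 held 1.15% of cHet_PD, 103 cells, and 0 cells of each other library. It was not counted in the neutrophil shares or in the interferon medians of the classes. The eosinophil-type cluster led by Prg2, Ear1, Epx and Ear2 held 0.682% of cKO_PD.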

How the results depend on the processing

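Alternative settings, 16 planned and 5 added later, were run over shares, 2-fold counts, named genes and list medians, and the cause of each move was not tested unless the construction shows it. Of 351 count values 65 moved and 0 reversed, of 2760 gene values 595 moved and 5 reversed, of 3800 list medians 833 moved and 20 reversed, and of 316 share ratios 33 moved and 7 reversed. TMM scaling reversed no value, and neither did the pseudocounts. With 1 clustering no mononuclear phagocyte class was formed, so its values are missing there. Share values are log2 ratios.

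With named immune cells as the denominator, shares depend on one another by construction: phagocytes went from 2.18 to -0.54 in cHet (PD against control) and from 1.29 to -1.42 in cKO. Neutrophils went to 1.45 in cHet and 2.38 in cKO, T/NK cells to -0.70 and -1.73, and cHet dendritic cells to -1.53. A mitochondrial cap of 10% gave phagocyte shares of 1.63 and 0.58 and neutrophil shares of 3.29, 4.23 and, between the PD libraries, 0.78. It also gave osteoclast genes in PD phagocytes 0.0800, Ctsk 1.00, fibroblast Lyz2 -0.0587, and the median of epithelial alarm and antimicrobial genes in epithelial cell, cKO_control vs cHet_control, became -0.0261. The common UMI floor removes shallow PD cells by construction and gave neutrophil shares of 1.39 in cHet, 4.29 in cKO and 2.46 between PD libraries against 4.16, 5.09 and 0.49. It gave cKO T/NK cells -1.07 and neutrophil glycolysis 0.00220. The median of interferon response in epithelial cell, cKO_PD vs cKO_control, became -0.0150, and the median of cell cycle in epithelial cell, difference of differences, -0.0244. Without the top 5% of doublet scores neutrophil shares were 6.87 in cKO, 0.79 between PD libraries and -1.40 between controls. Osteoclast genes of PD phagocytes then had 0.27, Ctsk 1.5 and the epithelial barrier difference of differences 0.0465.

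Clustering settings changed the PD neutrophil ratio to 0.29 at resolution 2.0, 0.82 with more variable genes, 0.28 with 1 clustering and 0.98 with cells thinned before clustering, where cHet neutrophils had 3.42. At resolution 2.0 the log2 ratio of fibroblast share, cKO_PD vs cKO_control, was -0.0362, the median of interferon response in epithelial cell, cKO_PD vs cKO_control, -0.0306, and the median of integrin alpha9beta1 ligands in epithelial cell, cKO_PD vs cKO_control, -0.0130. The epithelial barrier difference of differences was 0.0385 at resolution 0.5 and 0.0204 with at least 500 genes per barcode. Under the mean over cells the median of endothelial activation and adhesion in endothelial cell, cKO_PD vs cHet_PD, was 0.0801.

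The genes at least 2-fold apart in mononuclear phagocytes, cHet_PD vs cHet_control, numbered 788, and were 1227 with 20 UMIs as the minimum, 1966 with none, 285 in thinned cells and 488 with a pseudocount of 50 CPM. Those of cKO_PD vs cKO_control were 709, and 1293, 2084 and 180. The genes at least 2-fold apart in mononuclear phagocytes, cKO_PD vs cHet_PD, were 383, and 621, 854, 126 and 205. The genes at least 2-fold apart in mononuclear phagocytes, cKO_control vs cHet_control, were 130, and 352, 730 and 15. The Itga9 level in mononuclear phagocytes, cKO_PD vs cHet_PD, was -1.76, with -1.02 under that pseudocount and -3.30 after thinning, where cKO_PD held 0 UMIs, so its size is set by the 10 CPM added. Thinning gave Itga9 -2.68 between controls (main -1.42), where 1 cell of cKO_control held a UMI, so only the direction is read. Thinning turned the interferon median of cKO phagocytes from -0.80 to 0.60, but to -0.21 where the list members were kept as without thinning. It turned the lipid-associated genes of control phagocytes to -0.14. The median of integrin subunits in fibroblast, cKO_PD vs cKO_control, became -0.0359, and between controls 0.11. Between PD libraries it turned the median of glycolysis and hypoxia in neutrophil, cKO_PD vs cHet_PD, to 0.0406, endothelial activation to 0.0336, regulatory T cell genes to 0.12 and fibroblast Tnfrsf11b to 0.14, and between controls fibroblast Itgb1 to 0.11. With list members kept as without thinning, the osteoclast difference of differences in phagocytes was 0.050.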

Other observations

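Neutrophils of cKO_PD expressed less of several inflammatory genes than those of cHet_PD, as whole classes whose cells lay in different clusters, so the values hold that difference too. Cxcl3 was 12.5-fold lower (10.4 to 15.1), the inflammasome sensor Nlrp3 8.03-fold lower (7.28 to 8.87) and the interferon-induced Slfn5 45.4-fold lower (20.4 to 125). The adhesion subunit Itgam was 3.11-fold higher (2.79 to 3.46). In endothelium the chemokine Cxcl10 stood at 126, 1186, 241 and 284 CPM, so that its highest level was in cHet_PD. The vein-associated Lrg1 stood at 224, 26.4, 371 and 86.5 CPM there.

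In fibroblasts Ptgs2, the prostaglandin-making enzyme, stood at 126, 644, 15 and 569 CPM, and the osteoblast factor Sp7 at 8.05, 18.8, 13.8 and 123. T/NK cells held Tnfrsf9, an activation receptor, at 141, 1263, 111 and 563 CPM, and Foxp3, the regulatory T cell factor, at 38.4, 145, 11.4 and 23.8. In epithelium S100a8, an antimicrobial subunit, stood at 30.1, 1476, 95.6 and 1317 CPM. In endothelium, taken as background for free neutrophil RNA, it stood at 72.8, 156, 2.45 and 393 CPM, and in T/NK cells at 6.4, 140.3, 0 and 745. How much of the epithelial value was free RNA was not measured. In phagocytes Fn1 was 20.8-fold lower in cKO_control than in cHet_control (11.4 to 42.4) and Vcam1 4.89-fold higher (3.66 to 6.63). Vegfa was 7.03-fold lower in cKO_PD than in cHet_PD (5.38 to 9.35), and Chil3, which also led a neutrophil cluster, was 11.1-fold higher (8.84 to 14.0).

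The libraries did not hold the same kinds of cells. Unnamed clusters led by Grip1 and Trps1 (15.3%, 0.234%, 14.2% and 0.243% of kept cells), by Reg3g and Cbr2 (2.08%, 0.112%, 9.53% and 0.121%) and by Obp1a and Mup4 (0.0253%, 0%, 8.71% and 0%) lay mostly in control libraries. The cluster led by Grip1 and Trps1 had 0 fixed markers of its closest type among its top 50 genes and a median of 2056 UMIs. Its origin is unknown, and it is not read as a difference in tissue. Salivary gland cells made up 2.11%, 0.290%, 2.98% and 9.05% of kept cells, a ratio of 31.2 (21.1 to 48.2) between the PD libraries. Chondrocytes made up 2.08%, 0%, 0.209% and 1.36%, and osteoclasts were 0, 6, 1 and 11 cells. Differences in what was dissected could therefore shape the shares of every class, with bone-forming transcripts 3.71-fold higher in cKO_PD than in cHet_PD. Those values come from 1 library per group.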
